A study of Mus musculus with 15 samples.

How the data were processed

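RNA from inguinal white adipose tissue of 15 C57BL/6 mice aged 8 weeks was sequenced, 5 mice in each of 3 groups. The groups were taken from the sample titles and genotypes. WT mice had floxed LKB1 alleles (LKB1 F/F), KO mice had these alleles with Adipoq-Cre, a recombinase active in adipocytes, and dKO mice had Adipoq-Cre with floxed LKB1 and floxed HDAC4 alleles. The titles hold mouse labels and no replicate numbers, so replicates were numbered within each group only to name them, and no pairing of mice between groups was available. The labels give no batch or date. Barcode numbers 12 to 16 were all used for dKO and for no other group, so barcode and genotype cannot be told apart.

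Total RNA was purified with an RNeasy kit and libraries were made with NuGEN Ovation kits, per the labels' protocols. FastQC, Subread, featureCounts and edgeR were used on genome build mm9, per the submitters' processing notes, which give no versions. The strand setting, the aligner settings and the treatment of duplicate and multi-mapping reads are not given in the sources used here. Genes that overlap, or that share sequence with a paralog, may therefore have counts that belong partly to a neighbour.

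The deposited table gives, per the file headers, raw counts of reads per gene for each library, with gene coordinates and exons. It holds 37991 genes, of which 415 have no symbol and are named by their identifier. The counts were used as deposited. The same table gives CPM values normalized by the authors, per the file headers. The authors marked 21049 genes as low and 2 as high, the mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2, and the CPM of the other 16940 genes sums to between 999992 and 1000008 per library. Those CPM values were used only to see which genes the authors kept, and 30 further scaled columns of the same libraries were not used. The annotation at hand is of another build, so coordinates are those of the deposited table.

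Total counts ran from 1564004 to 21570688 per library. mt-Rnr1 and mt-Rnr2 took 33.5 to 50% of them, which left 911371 to 12689115 for all other genes. A gene near 1 CPM thus rests on few counts in the shallower libraries, and its fold change has a wide error.

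Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's expression filter with a minimum count of 10 and a minimum total of 15, which left 12188 genes. Library sizes were scaled by TMM. All 15 libraries entered one robust quasi-likelihood fit with a term per group and 12 residual degrees of freedom, so that all groups share one estimate of spread. KO was tested against WT, dKO against KO and dKO against WT, each two-sided, with a further test of any difference among the groups. P-values were adjusted by Benjamini-Hochberg over the 12188 genes and a gene was called at an adjusted p under 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of its F value. CPM in the text is scaled to the TMM library size and given as mean ± SD over the 5 mice of a group.

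Before the data were examined, 29 gene lists with 613 entries were fixed, along with the groups, tests, other settings to try and the rule for naming genes. Of these, 603 entries were matched and 2 symbols were absent; the others were older or newer names of a gene already in the same list. Lists with at least 5 tested members were tested against all other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at a preset correlation of 0.01 between genes and again with an estimated correlation. They were also tested against no change with fry. Camera and fry p-values were adjusted by Benjamini-Hochberg over the lists. Members were counted by the test over all genes and adjusted over the list alone. The mean log2 CPM of each list was compared between groups by exact two-sided permutation of the 5 and 5 libraries, where the smallest p possible is 0.00794.

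The naming rule took Stk11 (the gene of LKB1) and Hdac4 in every library. It took up to 8 of the largest rises and 8 of the largest falls per comparison among called genes with a mean log2 CPM of at least 1 and no overlap between the groups' libraries, leaving out predicted genes, pseudogenes and receptor segments. From each list it took up to 4 called members by p, or else up to 2 of the most abundant members as values. Ucp1, Cidea, Dio2, Cox8b, Elovl3, Ppargc1a, Prdm16, Adipoq and Lep were always included. One result that this rule selects is not reported here.

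The other settings fixed in advance were median-of-ratios size factors, no expression filter, DESeq2 1.42.0, limma voom with sample weights, a fit of only the 2 groups compared, summing of the libraries 1753 and 1753-2, covariates for lymphocyte, muscle and epithelial lists, and leaving out each library in turn. Added after seeing the data were the removal of both 1753 libraries (for lists also with an estimated correlation), removal of the mitochondrial ribosomal RNAs, the authors' kept genes, and thinning of all libraries to a common depth. The libraries 1753 and 1753-2 carry related mouse labels. They were kept as 2 mice because the series states 5 mice per group. Their counts do not settle this: they differed by more than sampling noise (chi-square per degree of freedom 2.50), as 2 libraries of 1 mouse would too.

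The fit was tested on simulated counts with known changes, made from the real libraries in 3 runs over 12138 genes. It called 52.8% of 2-fold changes and 94.9% of 4-fold changes for KO versus WT, 60.3% and 96.0% for dKO versus KO, and 56.8% and 95.2% for dKO versus WT. Of simulated changes of 1.5-fold, it called 12.7%, 18.0% and 12.6%. False calls made up 5.1%, 4.1% and 3.8% of calls. At 2-fold, 195, 380 and 185 genes had been changed, so these rates do not rank the comparisons. Whether they hold for the real dKO libraries was not tested. The biological coefficient of variation was 30.8% in dKO, against 20.6% in WT and 19.4% in KO. Comparisons that share a group were set against simulated unchanged groups. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for library measures and figures, and the R package data.table, version 1.17.8, for reading tables in R.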

Results

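Gene expression was measured in inguinal white adipose tissue, a subcutaneous fat depot, of 15 mice. WT mice carried floxed alleles of LKB1, a kinase that activates AMPK and its relatives and is encoded by Stk11. KO mice carried these alleles with Adipoq-Cre, so that LKB1 was targeted in adipocytes. In dKO mice floxed HDAC4, a class IIa histone deacetylase, was targeted as well. Each group had 5 mice. Whole tissue was sequenced, so each library also holds RNA of vessels, immune cells and other stromal cells. The series title names beige adipocytes, the thermogenic fat cells of subcutaneous depots, and the design asks how loss of LKB1 in adipocytes changes the tissue and how much of that is altered when HDAC4 is targeted too.

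Total counts per library were 2181109 to 4062909 in WT, 2969355 to 21570688 in KO and 1564004 to 12089891 in dKO. The largest total was that of KO replicate 1. Mean totals did not differ detectably between the groups, with exact two-sided permutation p of 0.318 or higher. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 took 33.5 to 50% of the counts. The share of mitochondrial messenger RNA among the other counts averaged 9.37% in WT, 11.8% in KO and 8.16% in dKO. By exact two-sided permutation tests (n = 5 each) p was 0.0159 for dKO against KO, 0.167 for KO against WT and 0.31 for dKO against WT, and none passed after adjustment over the 15 tests of library measures (0.238 for the lowest). Xist had 0 to 8 counts and the Y-linked genes 420 to 4302 in every library. The dKO libraries carried barcodes 12 to 16, which no library of another group had.

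The dKO libraries of the mice labelled 1753 and 1753-2 stood apart from the other 13. On the leading principal component, which held 30.2% of the variance, they scored 60.9 and 60.3, while the others lay between -39.9 and 12.6. Fasn, the fatty acid synthase, was at 6210 and 6187 CPM in them and at 465, 900 and 1079 CPM in the other dKO mice. They were counted as 2 mice because the series states 5 per group, and the counts do not settle whether they are. The biological coefficient of variation was 20.6% in WT, 19.4% in KO and 30.8% in dKO, and 17.1% in dKO without these libraries. In dKO, mean ± SD therefore covers 2 kinds of profile.

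Stk11 (ENSMUSG00000003068, mm9 chromosome 10, 79578548 to 79593427, 10 exons) was at 29.6 ± 6.33 CPM in WT, 18.0 ± 4.20 in KO and 19.4 ± 2.84 in dKO (SD, n = 5 each). In WT the libraries had 22.2, 37.8, 33.6, 24.8 and 29.4 CPM. In KO they had 19, 22.5, 11.6, 20.4 and 16.3 CPM, and in dKO 22.7, 19.3, 21.8, 16.6 and 16.6 CPM. The log2 fold change of KO against WT was -0.69 (SE 0.18), which did not pass with edgeR (adjusted p = 0.115). Over the alternatives this adjusted p ran from 0.0139 to 0.286, and it passed with DESeq2 (0.0311), with only the 2 groups compared (0.0466), with the lymphocyte covariate (0.0139) and without both 1753 libraries (0.0335). The log2 fold change of Stk11 was -0.63 for dKO against WT (adjusted p = 0.136) and 0.07 for dKO against KO (adjusted p = 0.973).

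Hdac4 is listed as 2 features. The larger (ENSMUSG00000026313, mm9 chromosome 1, 93829334 to 94044970, 27 exons) was at 12.2 ± 3.16 CPM in WT, 10.3 ± 2.16 in KO and 10.3 ± 0.794 in dKO. Its WT libraries had 11.2, 16.1, 12.2, 7.63 and 13.9 CPM, its KO libraries 11.2, 13.4, 8.17, 8.35 and 10.2, and its dKO libraries 10.7, 10.8, 11.2, 9.58 and 9.41. The log2 fold change of Hdac4 for dKO against KO was -0.03 (edgeR adjusted p = 0.990), and against WT -0.26 (adjusted p = 0.579). The neighbouring feature of 1 exon (ENSMUSG00000073617, chromosome 1, 93825362 to 93827753) was at 7.08 ± 1.29, 5.45 ± 1.24 and 5.49 ± 1.01 CPM. Counts per gene do not resolve single exons, the deleted exons are not given in the sources used here, and the tissue holds cells in which Adipoq-Cre is not active. The Hdac4 counts therefore do not check the dKO label.

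Targeting LKB1 in adipocytes went with a large rise of thermogenic genes. Ucp1 (ENSMUSG00000031710, chromosome 8), the uncoupling protein of brown fat mitochondria, was at 13.9 ± 9.67 CPM in WT and 489 ± 202 CPM in KO (SD, n = 5 each), 34.4-fold higher. Dio2 (ENSMUSG00000007682, chromosome 12), the deiodinase that activates thyroid hormone, rose 82.8-fold, from 2.27 ± 1.75 to 196 ± 104 CPM. Otop1, a proton channel, rose 5.88-fold to 69.3 ± 18.9 CPM, Gyk, the glycerol kinase, 5.28-fold, and S100b, a calcium-binding protein, 7.75-fold to 24.7 ± 9.97 CPM. Ppargc1a, a coactivator of mitochondrial biogenesis, rose 2.67-fold from 23.8 ± 4.11 to 62.9 ± 22 CPM. In log2 units the changes of Ucp1, Dio2 and Ppargc1a were 5.10 (SE 0.45, edgeR adjusted p = 2.81e-05), 6.37 (SE 0.52, 2.17e-05) and 1.42 (SE 0.24, 0.00769).

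Of the 22 tested members of the thermogenic list, 10 rose in KO and none fell, and 18 rose when adjusted over the list alone; 21 of 22 fold changes were positive. The other members that rose included Cox7a1 (2.57 on the log2 scale, SE 0.37, adjusted p = 0.00144) and Cox8b (1.44, SE 0.28, adjusted p = 0.0185), subunits of cytochrome c oxidase. The list lay above all other genes by camera (median log2 fold change 1.30, adjusted p = 5.10e-31; adjusted p = 0.00764 with an estimated correlation), and it rose by fry, which tests against no change (adjusted p = 0.000116). It was the only one of 26 lists tested to pass with an estimated correlation. Cidea, a lipid droplet protein of brown adipocytes, was at 10.3 ± 7.28 CPM in WT and 20.4 ± 4.56 in KO, a log2 fold change of 0.98 (SE 0.37) that did not pass (adjusted p = 0.36; over the alternatives 0.0359 with voom to 0.629). Prdm16, a regulator of brown adipocyte fate, had a log2 fold change of 0.80 (adjusted p = 0.181). Elovl3, a fatty acid elongase of brown fat, was below the expression filter, with 140, 16, 1, 2 and 0 counts in the KO libraries and 0 or 1 in each WT library. Without WT replicate 2, 3 or 4, or KO replicate 1, 2 or 3, Cox8b did not pass (adjusted p = 0.0585, 0.0635, 0.0731, 0.0707, 0.0598 and 0.0598).

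**Figure D1:**
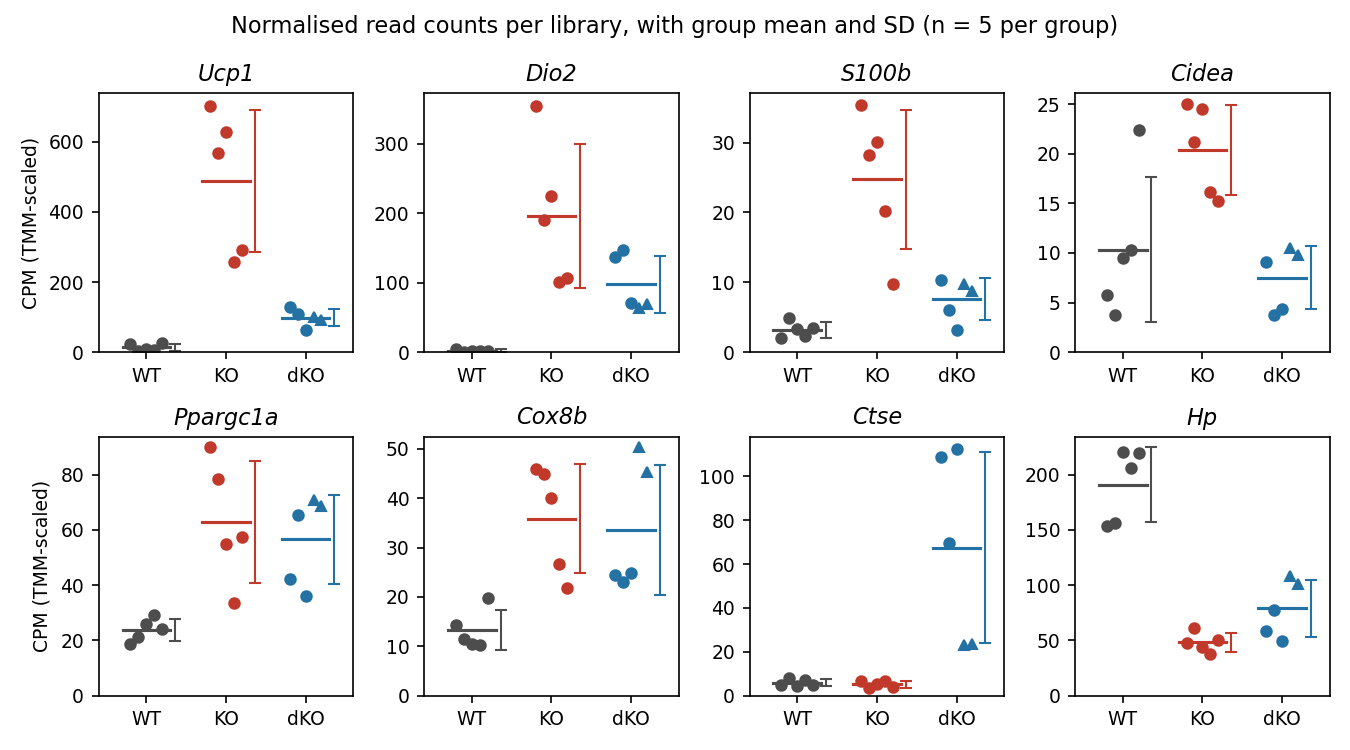
CPM of 8 genes in each of the 15 libraries by group, on linear axes from 0, with lines for group means, bars for SD and triangles for the dKO libraries 1753 and 1753-2. Ucp1 averaged 13.9 CPM in WT, 489 in KO and 98.5 in dKO.

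Genes of mitochondrial fuel oxidation were also higher in KO. Of 22 tested fatty acid oxidation genes, 5 rose (11 adjusted over the list alone; median log2 fold change 0.63), among them the acyl-CoA dehydrogenases Acadm (0.97, SE 0.16, edgeR adjusted p = 0.00394) and Acadl (1.03, SE 0.17, adjusted p = 0.00612). Of 16 tricarboxylic acid cycle genes, 3 rose (10 adjusted over the list alone; median 0.66), led by Sucla2, a succinyl-CoA synthetase subunit, at 157 against 56.9 CPM (adjusted p = 0.000403). Of 78 oxidative phosphorylation genes, 2 rose, Cox7a1 and Cox8b, which are also in the thermogenic list (2 adjusted over the list alone; median 0.42). Camera called all 3 lists (adjusted p = 1.04e-13, 1.86e-13 and 5.34e-15), and the calls were lost with an estimated correlation (adjusted p = 0.321, 0.321 and 0.617 with an estimated correlation). The 5 fatty acid oxidation genes were 2, Acadm and Acadl, without WT replicate 1, 2, 4 or 5 or KO replicate 1, 2 or 3, and 3 without WT replicate 3, KO replicate 4 or 5 or dKO replicate 2. Without any 1 of the same first 7 libraries the 3 tricarboxylic acid cycle genes were 1, Sucla2. The 2 oxidative phosphorylation genes were 1 without the 6 libraries named above for Cox8b. The 3 counts were 9, 12 and 11 without both 1753 libraries, and 2, 2 and 2 with the muscle covariate, where Acaa2, a thiolase (1.25 before and 1.24 with it), Slc25a20, an acylcarnitine carrier (0.75 and 0.77), and Idh3g, an isocitrate dehydrogenase subunit (0.80 and 0.84), did not pass (adjusted p = 0.0751, 0.0884 and 0.0856). Plin5, a perilipin of lipid droplets, rose 5.58-fold (adjusted p = 0.000187) and was the 1 of 20 triglyceride storage genes to rise. Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose 3.75-fold (adjusted p = 0.0218) and was the 1 of 20 glycolysis genes to rise. Pdk4 did not pass without WT replicate 2 or 5, or KO replicate 1, 3 or 5 (adjusted p = 0.0631, 0.0538, 0.0518, 0.0681 and 0.0625).

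Skeletal muscle genes varied from mouse to mouse. The mean log2 CPM of the list was 1.53 ± 1.80 in WT, 2.74 ± 1.32 in KO and 1.87 ± 1.29 in dKO (exact two-sided permutation p = 0.278 for KO against WT, n = 5 each, and 0.474 adjusted over the lists). Of its 14 tested genes, 0 passed with edgeR, DESeq2 or voom, and 0 had an unadjusted edgeR p under 0.05. Myh4, a fast myosin heavy chain, had a log2 fold change of 1.6 in KO (adjusted p = 0.847) and Myl1 of 1.08 (adjusted p = 0.650). Camera placed the list above other genes (median 1.46, adjusted p = 0.000142; adjusted p = 0.617 with an estimated correlation).

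Among the genes that fell in KO, Hp, haptoglobin, was at 191 ± 33.7 CPM in WT and 48.3 ± 8.75 in KO, 3.93-fold lower (log2 fold change -1.98, SE 0.20, edgeR adjusted p = 2.81e-05). Cyp2e1, a cytochrome P450, was 3.28-fold lower (488 ± 95.2 to 149 ± 55.5 CPM, adjusted p = 0.000886). Nnat, neuronatin, was 4.30-fold lower (266 ± 99 to 62.2 ± 24.8 CPM, adjusted p = 0.0144) and Bmp3, a bone morphogenetic protein, 2.83-fold lower (adjusted p = 0.0113). Pon1, a paraoxonase, rose 7.76-fold (2.42 ± 1.40 to 19.5 ± 4.04 CPM, adjusted p = 3.44e-05). Without KO replicate 1, Nnat and Bmp3 did not pass (adjusted p = 0.0533 and 0.0518).

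Macrophage genes lay lower in KO as a group. All 20 fold changes were negative (median log2 fold change -0.49, camera adjusted p = 8.63e-07, adjusted p = 0.321 with an estimated correlation). By mean log2 CPM of the list the libraries of the groups overlapped, with 4.26 to 5.44 in WT and 4.14 to 4.49 in KO. The highest was WT replicate 4. Singly, 0 of the 20 passed with edgeR, 3 fell when adjusted over the list alone, 8 had an unadjusted p under 0.05, and DESeq2 called 0 and voom 2. Lyz2, lysozyme, had a log2 fold change of -0.41 (edgeR adjusted p = 0.559) and Mrc1, the mannose receptor, of -0.36 (0.679). Camera also placed proliferation genes (0 of 24 passed, median -0.26, adjusted p = 0.00610), the class IIa HDAC, MEF2 and CRTC list (0 of 10, -0.16, 0.0178) and extracellular matrix genes (0 of 24, -0.29, 0.0196; 1 rose when adjusted over the list alone) below other genes. At an unadjusted edgeR p under 0.05, 3 proliferation and 2 class IIa genes were lower, and 3 matrix genes lower and 1 higher. DESeq2 and voom each called 1 matrix gene, higher in KO and so against the direction of the list, and 0 of the others. Camera placed glycolysis (median 0.36, adjusted p = 0.00943; 3 rose and 1 fell adjusted over the list alone) and cAMP-responsive genes (0.29, 0.0128; 3 rose and 1 fell adjusted over the list alone) above. With an estimated correlation none of these 5 passed (adjusted p = 0.875 with an estimated correlation for extracellular matrix and 0.617 for the others). Of 18 cAMP-responsive genes, Pde4d, a phosphodiesterase (log2 fold change 1.13, adjusted p = 0.00976), and Jun (1.05, adjusted p = 0.0464) rose. Jun overlapped between the groups and did not pass without any 1 of WT replicates 1 to 5, KO replicates 1, 3 and 5 or dKO replicates 1, 2, 3 and 5 (adjusted p = 0.0510 to 0.173).

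No other list was called by camera for KO against WT, although cholesterol synthesis (0.00563) and triglyceride storage (0.0194) were, both higher, without both 1753 libraries (adjusted p = 0.632 and 0.728 with an estimated correlation). Adipocyte identity genes had a median log2 fold change of 0.11 (adjusted p = 0.0782; 1 of 19 rose adjusted over the list alone), with Adipoq, adiponectin, at 409 CPM in WT and 336 in KO (-0.28, edgeR adjusted p = 0.637) and Lep, leptin, at 320 and 235 CPM (-0.44, adjusted p = 0.839). The medians were 0.11 for triglyceride storage (adjusted p = 0.0575), 0.46 for cholesterol synthesis (0.0793) and -0.18 for lipogenesis (0.746; 2 rose adjusted over the list alone). They were -0.20 for preadipocytes (0.128), -0.02 for T and B cells (0.460), 0.08 for the LKB1 complex and AMPK-related kinases (0.746; 1 fell adjusted over the list alone), 0.12 for interferon response (0.746), -0.07 for endothelium (0.746) and -0.06 for Schwann cells (0.746). For smooth muscle (-0.05, adjusted p = 0.833) and red cells (-0.12, 0.836) the median and the camera direction differed in sign, as for stress response genes (0.03, 0.976). Secreted factors (-0.00, 0.836) and reported beige markers (-0.08, 0.976) did not pass. Too few genes were tested for epithelium (2, median -0.37), skin (1, Sbsn at -1.17) and sex-linked genes (4, -0.05).

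In all, 76 genes passed for KO against WT (53 higher and 23 lower; 1163 at an unadjusted p under 0.05), and in 69 of them the groups did not overlap. Among genes called for a difference this is expected; in a gene not chosen for one, chance gives it with probability 0.00794. The count was 41 without WT replicate 4, WT replicate 5 or KO replicate 3, and 36 without KO replicate 1. It was 163 with DESeq2, 299 with voom and 270 without both 1753 libraries, with all 76 genes among these 270.

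**Figure D2:**
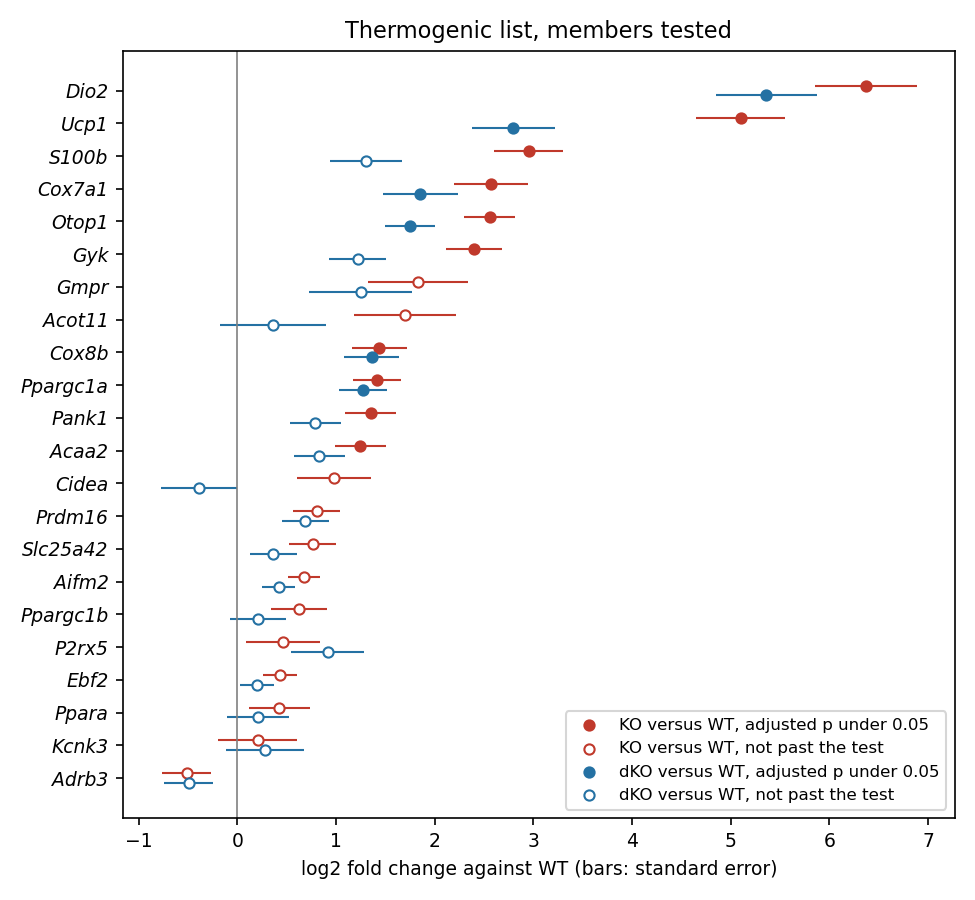
Log2 fold changes against WT of the 22 tested thermogenic genes in KO and dKO, with SE bars and filled points for an adjusted p under 0.05. In KO 21 of 22 were above 0.

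When HDAC4 was targeted together with LKB1, Ucp1 was lower than with LKB1 alone. It was at 98.5 ± 23.6 CPM in dKO against 489 ± 202 in KO, 4.95-fold lower (log2 fold change -2.31, SE 0.39, n = 5 each, edgeR adjusted p = 0.0393), and every dKO library lay below every KO library. S100b was 3.14-fold lower (7.59 ± 3.00 against 24.7 ± 9.97 CPM; -1.65, SE 0.31, adjusted p = 0.0482), with overlap between the groups. Cidea was at 7.51 ± 3.20 CPM in dKO and 20.4 ± 4.56 in KO without overlap, but did not pass (-1.37, SE 0.37, adjusted p = 0.368). Dio2 was at 97.8 ± 41.0 CPM in dKO (-1.01, adjusted p = 0.696), and Ppargc1a (-0.15), Cox8b (-0.08) and Prdm16 (-0.11) had small differences that did not pass. Of the 22 thermogenic genes, 2 fell, 7 when adjusted over the list alone, and 19 fold changes were negative (median -0.42, camera adjusted p = 4.60e-10; adjusted p = 0.382 with an estimated correlation). Over the alternatives the log2 fold change of Ucp1 ran from -2.47 to -2.14 and its adjusted p from 2.01e-06 with DESeq2 to 0.185 without both 1753 libraries. Ucp1 did not pass without KO replicate 1, 2 or 3 (0.103, 0.0949 and 0.0893) or any 1 of dKO replicates 1 to 5 (0.0540, 0.112, 0.0854, 0.15 and 0.172). With 1753 and 1753-2 summed to 1 mouse, neither Ucp1 (-2.29, adjusted p = 0.172) nor S100b (-1.71, adjusted p = 0.103) passed. S100b did not pass without any 1 of WT replicates 1 to 5, KO replicates 1 to 4 or dKO replicates 2 to 5 (0.0531 to 0.195).

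The largest rise in dKO against KO was that of Ctse, the aspartic protease cathepsin E. It was at 67.6 ± 43.8 CPM in dKO, 5.23 ± 1.62 in KO and 5.96 ± 1.59 in WT, 12.2-fold above KO (log2 fold change 3.61, SE 0.46, edgeR adjusted p = 0.00230), and it passed under all 28 alternatives. The UDP-glucuronosyltransferase genes Ugt1a6a (2.44 ± 0.747 to 10.3 ± 2.63 CPM, 4.33-fold, adjusted p = 0.00230) and Ugt1a5 (2.46 ± 1.85 to 14.7 ± 4.63 CPM, 5.08-fold, adjusted p = 0.0393) rose; these genes overlap and share exons, so which of them rose is uncertain. Fmod, the matrix protein fibromodulin, was 2.93-fold lower in dKO (5.66 ± 0.837 to 1.98 ± 0.646 CPM, adjusted p = 0.0386) and D2hgdh, a mitochondrial dehydrogenase, 1.99-fold lower (24.8 ± 3.32 to 12.4 ± 1.85 CPM, adjusted p = 0.0393). The predicted genes Gm15369 (log2 fold change 3.29) and Gm15372 (2.84), chosen after their values were seen, rose as well (adjusted p = 0.00163 each). All 7 of these genes lie on chromosome 1, which also holds Hdac4 and has 6.14% of the tested genes. The 2 predicted genes lie within the Ugt1a locus, so the 7 make 4 loci. Ucp1 and S100b, the other 2 that passed, lie on other chromosomes. Ugt1a5 did not pass without WT replicate 1 or 5, KO replicate 1, 3, 4 or 5, or dKO replicate 2, 3 or 4 (adjusted p = 0.0569 to 0.118), nor Fmod without WT replicate 1, KO replicate 1, 2, 4 or 5, or dKO replicate 1, 3, 4 or 5 (0.0536 to 0.145). D2hgdh passed without WT replicate 3 or 4 but not without any 1 of the other 13 libraries (0.0531 to 0.168).

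**Figure D3:**
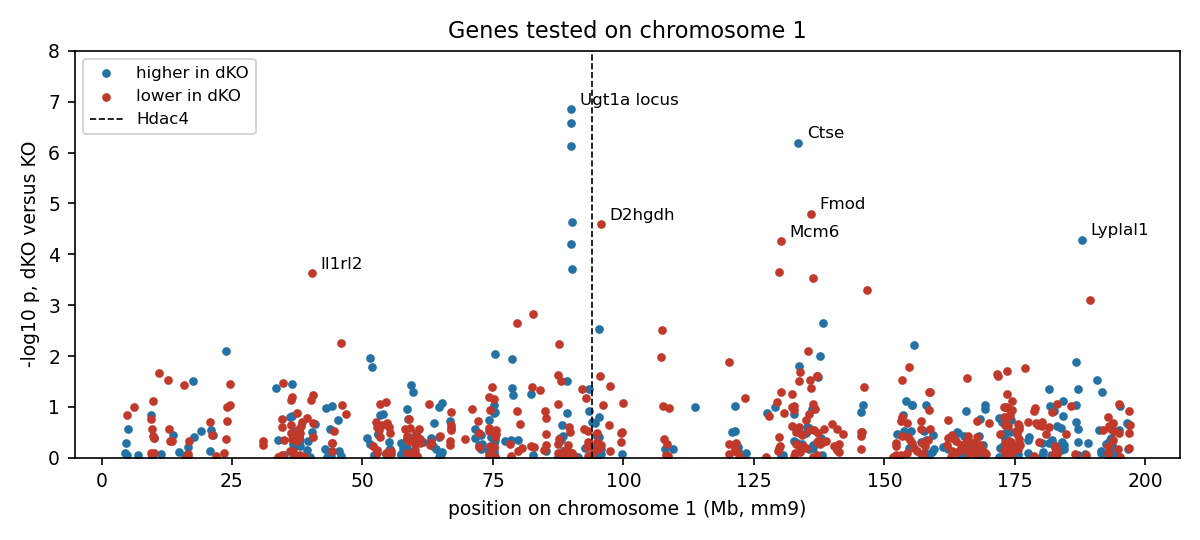
Unadjusted p (as minus log10) of dKO against KO for each tested gene on chromosome 1 by its mm9 position, with the position of Hdac4 as a dashed line. The 7 genes that passed are among 16 with p under 0.001 on this chromosome.

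Lists of lipid synthesis, lymphocytes, muscle, stress response and cAMP response were called by camera for dKO against KO, while edgeR called 0 of their members. Lipogenesis genes had a median log2 fold change of 0.88 (camera adjusted p = 0.000116), with Fasn at 1.51 (edgeR adjusted p = 0.790), and cholesterol synthesis genes of 0.64 (0.00422; 1 rose adjusted over the list alone). T and B cell genes had a median of -0.37 (1.39e-07), with the B cell receptors Cd22 at -0.41 and Cr2 at -0.40, and muscle genes of -2.0 (0.00324). The stress response (0.23, adjusted p = 0.00324; 1 rose adjusted over the list alone) and cAMP-responsive lists (-0.42, 0.0353) were called as well. At an unadjusted edgeR p under 0.05 there were 8 lipogenesis, 2 cholesterol, 2 lymphocyte, 2 stress, 3 cAMP-responsive and 0 muscle genes; DESeq2 called 1 stress gene, and voom 0. None of these 6 passed with an estimated correlation (adjusted p = 0.946 with an estimated correlation for each). Several turned without both 1753 libraries: lipogenesis was then lower in dKO than in KO (adjusted p = 0.00800), cholesterol synthesis lower (0.00281) and T and B cells higher (0.0217). Oxidative phosphorylation (9.58e-30), the tricarboxylic acid cycle (1.07e-14), fatty acid oxidation (3.67e-12) and thermogenic genes (4.02e-15) were then all lower in dKO, and the stress (0.961) and cAMP-responsive (0.909) lists were not called. With an estimated correlation no list passed without the pair (adjusted p = 0.126 or higher with an estimated correlation; 7 lists had an unadjusted p under 0.05).

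With all libraries, camera did not call the other lists for dKO against KO. The medians were 0.15 for oxidative phosphorylation (adjusted p = 0.793), 0.06 for the tricarboxylic acid cycle (0.437), -0.03 for fatty acid oxidation (0.499), 0.07 for glycolysis (0.540), 0.16 for adipocyte identity (0.147) and 0.21 for triglyceride storage (0.604). They were -0.23 for macrophages (0.218), 0.23 for extracellular matrix (0.231), 0.13 for red cells (0.226), -0.12 for interferon response (0.551), 0.00 for endothelium (0.604), 0.16 for smooth muscle (0.702) and 0.10 for Schwann cells (0.832). The LKB1 complex (0.03, adjusted p = 0.795), reported beige markers (-0.12, 0.838), proliferation (0.04, 0.838; 1 fell adjusted over the list alone), class IIa HDACs (-0.01, 0.838), preadipocytes (0.03, 0.900) and secreted factors (0.10, 0.900; 1 fell adjusted over the list alone) did not pass. The camera direction was down, against the sign of the median, for the tricarboxylic acid cycle, glycolysis, red cells, endothelium (0.00025), preadipocytes and secreted factors. Without both 1753 libraries glycolysis (5.98e-08), triglyceride storage (0.000736), secreted factors (0.00281), red cells (3.45e-06) and endothelium (0.0107) were called lower in dKO than in KO, and epithelium higher (2.65e-06). With an estimated correlation none of these calls remained. Medians of lists too small to test were 1.26 for epithelium, 0.51 for skin and 0.06 for sex-linked genes.

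In all, 9 genes passed for dKO against KO (5 higher and 4 lower; 752 at an unadjusted p under 0.05), 8 of them without overlap of the groups. The count was 5 without WT replicate 1, KO replicate 2, KO replicate 4 or dKO replicate 2, 3, 4 or 5, 4 without KO replicate 1 and 13 without dKO replicate 1. It was 37 with DESeq2, 9 with voom, 4 with 1753 and 1753-2 summed and 19 without both, 5 of them shared with the 9.

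Compared with WT, dKO mice still had higher levels of thermogenic genes. Dio2 was 41.1-fold higher (log2 fold change 5.36, SE 0.51, n = 5 each, edgeR adjusted p = 0.000210), Ucp1 6.94-fold (2.80, SE 0.42, adjusted p = 0.00457) and Otop1 at 38.7 ± 15.3 against 11.7 ± 2.18 CPM (1.75, SE 0.26, adjusted p = 0.00298). Of 22 thermogenic genes, 6 rose, 14 when adjusted over the list alone (median 0.81; camera adjusted p = 9.15e-13; adjusted p = 0.209 with an estimated correlation; 0.0141 by fry against no change). Of the 6, 3 passed without WT replicate 1, 2 or 3 or dKO replicate 4 or 5, with 1753 and 1753-2 summed, with voom and with the lymphocyte covariate, and 2 without both 1753 libraries. Cidea was at 7.51 ± 3.20 CPM in dKO and 10.3 ± 7.28 in WT (-0.39, adjusted p = 0.675), and Prdm16 at 18.6 and 11.6 CPM (0.69, adjusted p = 0.201). Ppargc1a (1.27, SE 0.24, adjusted p = 0.0218) and Cox8b (1.36, adjusted p = 0.0297) rose. Without both 1753 libraries the log2 fold change of Ucp1 was 2.81 and did not pass (adjusted p = 0.0886, the highest over the alternatives; the lowest was 6.18e-10, with DESeq2 on all libraries). Ppargc1a did not pass without WT replicate 1, 2, 3 or 5 or dKO replicate 4 or 5 (0.0553 to 0.0747), nor Cox8b (0.0714 to 0.0979) or Cox7a1 (0.0637 to 0.0961) without WT replicates 1 to 4 or dKO replicate 4 or 5, each left out singly.

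Among other genes, Ctse was 11.1-fold higher in dKO than in WT (log2 fold change 3.47, SE 0.46, edgeR adjusted p = 0.00217) and Pon1 rose by 2.13 on the log2 scale (SE 0.32, adjusted p = 0.00343). Il1rl2, a receptor of the interleukin 1 family on chromosome 1, was 2.89-fold lower (25.7 ± 7.69 to 8.82 ± 1.43 CPM, adjusted p = 0.00185), and Hp 2.39-fold lower (78.9 ± 25.8 CPM in dKO, adjusted p = 0.00391). Aldh3b2, an aldehyde dehydrogenase, rose by 2.01 (SE 0.34, adjusted p = 0.00801) and Plin5 by 1.87 (SE 0.31, adjusted p = 0.00707). The matrix protein gene Smoc2 had a log2 fold change of -1.09 (SE 0.19, adjusted p = 0.00801), Itgbl1 of -1.54 (adjusted p = 0.00994) and Nnat of -2.19 (SE 0.38, adjusted p = 0.0142). Nnat did not pass without dKO replicate 4 (adjusted p = 0.0634), and without both 1753 libraries Aldh3b2, Plin5, Smoc2, Itgbl1 and Nnat did not pass (0.0830, 0.0886, 0.0901, 0.0797 and 0.108). Adipoq (-0.13) and Lep (-0.00, adjusted p = 0.997) did not pass.

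Metabolic lists were above other genes in dKO against WT by camera. The medians were 0.58 for oxidative phosphorylation (2 of 78 rose, 2 adjusted over the list alone; camera adjusted p = 3.27e-14), 0.53 for fatty acid oxidation (2 of 22, 9 adjusted over the list alone; 2.32e-10) and 0.74 for the tricarboxylic acid cycle (1 of 16, 14 adjusted over the list alone; 3.58e-10). They were 1.17 for cholesterol synthesis (0 of 18, 10 adjusted over the list alone; 4.63e-05), 0.32 for adipocyte identity (0 of 19, 2 adjusted over the list alone; 0.00208), 0.66 for lipogenesis (0 of 19, 2 adjusted over the list alone; 0.00675) and 0.31 for triglyceride storage (1 of 20, 2 adjusted over the list alone; 0.0102). With an estimated correlation none of these passed (adjusted p = 0.546 to 0.667 with an estimated correlation). For the lists with 0 genes called by edgeR, DESeq2 called 4 cholesterol, 2 adipocyte and 1 lipogenesis gene and voom 0, and at an unadjusted p under 0.05 there were 12 cholesterol, 7 adipocyte (6 higher and 1 lower) and 6 lipogenesis genes. The genes called in the oxidation lists were Cox7a1 and Cox8b, Acadm and Acadl, and Sucla2. Each library left out singly, Acadm did not pass without WT replicate 1, 2, 4 or 5 or dKO replicate 4 or 5 (0.0716 to 0.106), Acadl without WT replicates 1 to 5 or dKO replicate 4 or 5 (0.0745 to 0.108), and Sucla2 without WT replicates 1 to 5, KO replicate 1, 2 or 5, or dKO replicate 2, 4 or 5 (0.0574 to 0.155). With 1753 and 1753-2 summed none of these 5 passed (0.0849 to 0.132), and without dKO replicate 1 the lists had 4, 6 and 5 called genes. Most of the list calls hang on the mice 1753 and 1753-2. Without both, oxidative phosphorylation (adjusted p = 0.295), cholesterol synthesis (0.788), adipocyte identity (0.855) and triglyceride storage (0.332) were not called, lipogenesis was lower in dKO than in WT (0.000547), and the tricarboxylic acid cycle (0.0284) and fatty acid oxidation (0.0380) stayed higher. No list passed without the pair with an estimated correlation (adjusted p = 0.207 or higher with an estimated correlation; 4 lists had an unadjusted p under 0.05).

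Macrophage genes lay lower in dKO than in WT. Singly, 0 of 20 passed with edgeR, 11 fell when adjusted over the list alone, 13 had an unadjusted p under 0.05, and DESeq2 called 1 and voom 0. The median log2 fold change was -0.66 (camera adjusted p = 5.92e-09; adjusted p = 0.303 with an estimated correlation). Lyz2 had a log2 fold change of -0.78 (edgeR adjusted p = 0.10) and Mrc1 of -0.24 (adjusted p = 0.643). The mean log2 CPM of the list was 4.70 ± 0.47 in WT, 4.29 ± 0.15 in KO and 4.10 ± 0.06 in dKO (exact two-sided permutation p = 0.00794 for dKO against WT, the smallest possible, and 0.0767 adjusted over the lists). Without both 1753 libraries the macrophage list was still called by camera (adjusted p = 1.29e-07), but it did not pass with an estimated correlation.

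T and B cell genes were below other genes in dKO against WT (median -0.47, camera adjusted p = 1.37e-07, adjusted p = 0.562 with an estimated correlation), and 1 of 22 fell, Glycam1, an adhesion molecule of lymph node vessels (-0.99, edgeR adjusted p = 0.0405). The class IIa HDAC list (median -0.24, 0.0105; 0 of 10 genes by edgeR, DESeq2 or voom and 0 at an unadjusted p under 0.05) and proliferation (1 of 24 fell, the replication helicase gene Mcm6, -0.24, 0.0160) were below, and stress response genes above (1 of 17 rose, Sesn2, a sestrin; 2 adjusted over the list alone; median 0.17, 0.0188). These were lost with an estimated correlation (adjusted p = 0.562, 0.667 and 0.562 with an estimated correlation). Without both 1753 libraries none of these 4 was called (adjusted p = 0.237, 0.391, 0.163 and 0.802). Glycam1 did not pass without WT replicate 1, 4 or 5, KO replicate 2, 4 or 5, or dKO replicates 2 to 5, each left out singly (0.0524 to 0.117), nor Mcm6 without WT replicate 1, 2 or 5 or dKO replicate 4 or 5 (0.0519 to 0.0643). Sesn2 passed without KO replicate 3 or dKO replicate 3 but not without any 1 of the other 13 libraries (0.0525 to 0.163).

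Lists not called for dKO against WT had medians of 0.39 for glycolysis (adjusted p = 0.0764), -0.10 for preadipocytes (0.135), -0.02 for endothelium (0.358), 0.09 for smooth muscle (0.440), 0.14 for the LKB1 complex (0.491), -0.05 for secreted factors (0.658), and -0.20, -0.04 and -0.09 for reported beige markers, interferon response and Schwann cells (0.861 each). The median and the camera direction differed in sign for muscle (-0.44, adjusted p = 0.380), red cells (0.13, 0.380), extracellular matrix (0.03, 0.440; 1 fell adjusted over the list alone) and cAMP-responsive genes (-0.15, mean 0.02, 0.600). Of the last, Pde4d rose (0.90, adjusted p = 0.0460), but did not pass without any 1 library other than dKO replicate 3 (0.0549 to 0.154). With both 1753 libraries left out, extracellular matrix (2.33e-05), red cells (1.23e-05), secreted factors (0.000149) and endothelium (0.00163) were called lower in dKO than in WT, and cAMP-responsive (0.00617), epithelial (0.000547) and interferon genes (0.0435) higher. None of these passed with an estimated correlation. For the lists too small to test the medians were 0.89 for epithelium (2 rose adjusted over the list alone), -0.65 for skin and 0.12 for sex-linked genes. In all, 75 genes passed for dKO against WT (52 higher and 23 lower; 1769 at an unadjusted p under 0.05), 64 of them without overlap. The count was 36, 35, 33, 31 and 37 without WT replicates 1 to 5 in turn, 240 without dKO replicate 1, and 27 and 28 without dKO replicates 4 and 5. It was 220 with DESeq2, 26 with voom, 26 with 1753 and 1753-2 summed and 30 without both.

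**Figure D4:**
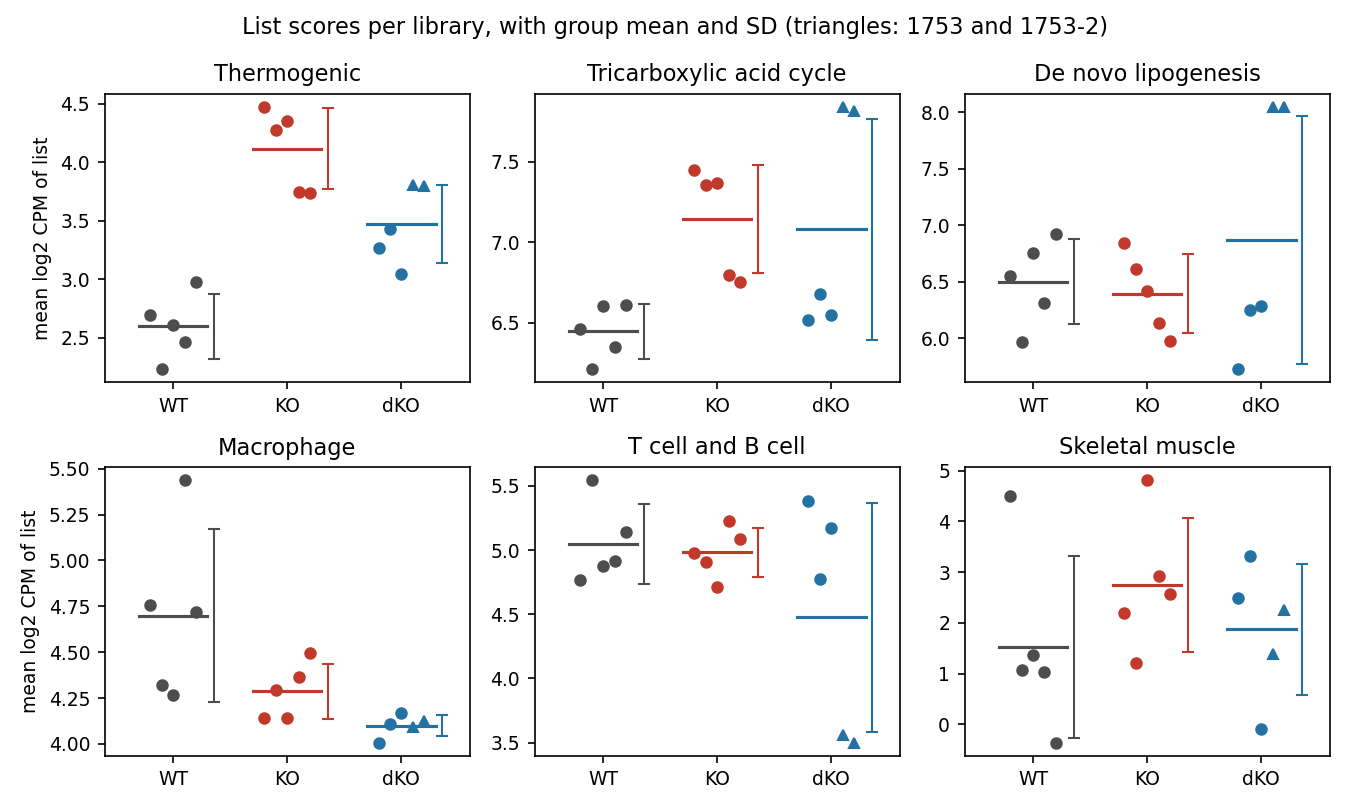
Mean log2 CPM of 6 gene lists in each library by group, with lines for group means and bars for SD. The thermogenic list averaged 2.6 in WT, 4.12 in KO and 3.47 in dKO.

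The design also asks whether genes altered by loss of LKB1 moved back when HDAC4 was targeted too. Ucp1 and S100b were the 2 genes that rose in KO against WT and fell in dKO against KO. Of the 53 genes higher in KO, 46 had lower levels in dKO than in KO, 25 of them at an unadjusted p under 0.05; their median log2 fold change was 1.30 for KO against WT and 0.86 for dKO against WT. Of the 23 lower in KO, 21 had higher levels in dKO, 10 at an unadjusted p under 0.05, and 0 passed with edgeR; their medians were -1.28 and -0.68. Hp was at 191, 48.3 and 78.9 CPM and Cyp2e1 at 488, 149 and 317 CPM in WT, KO and dKO. The KO libraries enter both comparisons, which alone sends genes back. Across genes, which are not independent replicates, the fold changes of both comparisons correlated at r = -0.299, against -0.491 in simulated unchanged groups. The covariance was -0.0354 against a simulated -0.0397. With the KO libraries split so that each comparison had its own, a median of 88.2% of called genes lay toward WT in dKO. The share ran from 54.4 to 100% over 20 fits, and a median of 0 genes (0 to 2) passed both ways. Over all genes the correlation in these fits averaged -0.00992 (-0.185 to 0.198), so no general movement back was seen with all dKO libraries. These fits were not repeated without both 1753 libraries. Independent lists would share 0.0174 genes among those higher in KO and 0.00944 among those lower.

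The count of 2 was 1 without any 1 of WT replicates 1 to 5, KO replicate 4 or dKO replicate 1. It was 0 without KO replicate 1, 2 or 3 or dKO replicate 2, 3, 4 or 5, where 149, 170, 124, 163, 163, 140 and 140 genes had both unadjusted p under 0.05 in edgeR, against 159 with all libraries. DESeq2 gave 6 genes, voom 1, and the fit without both 1753 libraries 7. In the fit without that pair, 446 genes had opposite changes at both unadjusted p under 0.05 in edgeR. The extent of movement back thus depends on the pair, and the shared KO libraries stay in that count.

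KO and dKO shared many differences from WT. Dio2, Ucp1, Otop1, Pon1, Plin5 and Ppargc1a were among 24 genes higher in both, and Hp and Nnat among 5 lower in both. Independent lists would share 0.226 and 0.0434 genes. The WT libraries enter both comparisons: the correlation of fold changes across genes was 0.633 against 0.523 in simulated unchanged groups, and the covariance 0.0922 against 0.0434. With the WT libraries split, the correlation averaged 0.278 and 0 to 10 genes passed in both comparisons (median 4.5), and 0 in simulated unchanged groups. Any difference among the groups was called for 84 genes by edgeR, 54 without WT replicate 4 and 193 without dKO replicate 1.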

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

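No test of a cause was run for the single values in this part; the gap measure was fixed before the data were examined. In each group of 5 libraries the distance of the highest or lowest library from its nearest neighbour was divided by the range of the group, and values above the critical value of 0.71 are listed. This was so in 17 of 246 groups, where chance gives about 5%, and in 9 of 147 groups of single genes.

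Among genes, Pon1 was lowest in WT replicate 2 (gap 0.717 of the range) and highest in dKO replicate 2 (0.788). Cyp2e1 was lowest in dKO replicate 1 (0.749), and Pde4d was highest there (0.770). Mt2, a metallothionein, was highest in KO replicate 5 (0.728), and Prdm16 in WT replicate 3 (0.863). Adipoq was lowest in KO replicate 4 (0.741), Ugt1a6a highest in WT replicate 3 (0.801) and Sesn2 lowest in KO replicate 3 (0.802).

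The total count of KO replicate 1, 21570688, stood above that of the next KO library, 6048092 (0.834). By mean log2 CPM, preadipocyte genes were lowest in dKO replicate 1 (0.889), secreted factors highest in WT replicate 3 (0.761), and glycolysis genes lowest in WT replicate 2 (0.755). Epithelial genes were highest in WT replicate 1 (0.837). Skin genes were highest in WT replicate 1 (0.830) and in dKO replicate 5 (0.834), and endothelial genes lowest in WT replicate 2 (0.889).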

How the results depend on the processing

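The settings without both 1753 libraries, without mitochondrial ribosomal RNA, with the authors' kept genes and with thinned counts were chosen after seeing the data. No named gene that passed changed direction under any alternative. For KO against WT, 17 of 29 such genes passed under all of them, among them Ucp1, Dio2, Otop1, Gyk, S100b, Ppargc1a, Acadm, Acadl, Sucla2, Hp and Cyp2e1. For dKO against WT, 6 of 26 did (Ctse, Dio2, Hp, Il1rl2, Otop1 and Pon1), and for dKO against KO, Ctse did. Libraries hold 911371 to 12689115 counts outside mitochondrial ribosomal RNA, so small changes of low genes may have been missed. Recovery by expression level was not tested. Leaving out libraries lowered some counts of genes and raised others. Without both 1753 libraries the biological coefficient of variation of dKO was 17.1% in place of 30.8%; no cause of the changes below was tested beyond this. A sex covariate was not run because Xist had 0 to 8 counts and Y-linked genes were counted in every library, as in males, and a pseudocount does not apply to counts. No paired analysis was possible because the labels give no replicate numbers.

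Against 76, 9 and 75 genes for KO against WT, dKO against KO and dKO against WT, DESeq2 gave 163, 37 and 220, the fit of only the 2 groups compared 224, 5 and 32, and removal of both 1753 libraries 270, 19 and 30. The lymphocyte covariate gave 373 for KO against WT and 48 for dKO against KO. Its score was 3.56 and 3.50 in 1753 and 1753-2, against 4.71 to 5.54 in the other libraries. This covariate therefore also separates that pair from the rest. Voom gave 299 for KO against WT and 26 for dKO against WT, and the muscle covariate 46 and 45. Summing 1753 and 1753-2 gave 4 for dKO against KO and 26 for dKO against WT, and thinning 2 and 33. Without the expression filter dKO against KO gave 19. All 76, 9 and 73 of the 75 genes were also called by DESeq2.

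Against 2 genes that changed KO against WT and the opposite way dKO against KO, DESeq2 gave 6, the lymphocyte covariate 24 and removal of both 1753 libraries 7. The covariate and the removal had 453 and 446 genes with opposite changes at both unadjusted p under 0.05 in edgeR, against 159 in the main fit. Voom, only the 2 groups compared, the muscle covariate and the authors' kept genes gave 1. Summing, the epithelial covariate and thinning gave 0, with 137, 143 and 131 genes at both unadjusted p under 0.05 in edgeR. Against 84 genes with any difference, DESeq2 gave 254, voom 173, the lymphocyte covariate 360, removal of both 1753 libraries 213 and thinning 55.

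With 1 library left out, the counts were 36 to 93 for KO against WT, 4 to 13 for dKO against KO, 27 to 240 for dKO against WT, 0 to 2 for the opposite changes and 54 to 193 for any difference; the report names the libraries that moved one of these counts by over 1.5 times.

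Against 11, 7 and 13 lists called by camera, 1, 0 and 0 passed with an estimated correlation (4, 1 and 2 unadjusted), 1, 0 and 1 by directional fry (4, 1 and 4 unadjusted) and 4, 1 and 2 by mixed fry. Without both 1753 libraries 14 lists were called for dKO against KO, and with an estimated correlation 1, 0 and 0 passed (5, 7 and 4 unadjusted).

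Reversed signs were found only for genes that did not pass. For dKO against KO, Hdac4 (-0.03) was 0.0032 on summing, 0.071 with the lymphocyte covariate and 0.058 without both 1753 libraries; Adipoq (0.15) was -0.030 with the lymphocyte covariate and -0.028 without both 1753 libraries; Prdm16 (-0.11) was 0.0057 with the epithelial covariate. Lep (0.44) was -0.20 with voom, -0.28 with the lymphocyte covariate and -0.47 without both 1753 libraries. For dKO against WT, Lep (-0.00) was 0.040 without the filter, 0.065 with the epithelial covariate and 0.0076 with the authors' kept genes.

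With 1 library left out, dKO against KO ran from -0.27 to 0.035 for Cox8b, -0.093 to 0.088 for Hdac4, -0.30 to 0.025 for Ppargc1a and -0.035 to 0.16 for Stk11. For dKO against WT, Cidea ran from -0.60 to 0.11 and Lep from -0.31 to 0.20.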

Other observations

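The tests of chromosome 1, of adipocyte share, of shared KO libraries, of the 1753 pair and of other splits were chosen after the results were seen; those with the muscle covariate and with thinned counts on thermogenic genes in KO were fixed before theirs.

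The mice 1753 and 1753-2 differed from the other dKO mice in several gene groups at once. Their mean log2 CPM of lipogenesis genes was 8.05 and 8.05, against 5.73, 6.25 and 6.29 in dKO replicates 1 to 3. For oxidative phosphorylation it was 6.42 and 6.33 against 5.07, 5.15 and 5.00, and for the tricarboxylic acid cycle 7.84 and 7.81 against 6.52, 6.68 and 6.55. T and B cell genes, which mark the lymph node within this fat depot, were at 3.56 and 3.50 against 5.38, 4.77 and 5.17. Thermogenic genes were at 3.81 and 3.80 against 3.26, 3.43 and 3.04. Ctse was at 23.1 and 23.6 CPM against 109, 69.6 and 113 CPM. The pair correlated at 0.987 across genes, above the 0.879 to 0.983 of the 29 other pairs within groups, and its chi-square per degree of freedom of 2.50 compares with 3.08 to 30.6 in those. Chi-square per degree of freedom grows with the counts of a pair, so it does not rank pairs of unlike depth. KO replicate 4 with dKO replicate 3, both with fewer counts and of different groups, had 2.49. Whether they are 1 mouse or 2 is open, and no cause was tested.

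Chromosome 1 held many of the differences of dKO. Of 41 genes with p under 0.001 for dKO against KO, 16 lay there, where 10000 circular shifts of the gene order gave a mean of 2.52 (one-sided permutation p = 0.0158), and 22 of 132 for dKO against WT (permutation p = 0.00220). For KO against WT it was 7 of 117 (permutation p = 0.529). Over 20 chromosomes only the value of dKO against WT would pass. Shifts small enough to keep the counted genes on chromosome 1 score as high as the real order, however many genes there are. This p therefore depends on where the outermost genes lie, and its size does not rank the comparisons. Counting neighbours once still left 12 loci, against a mean of 2.27 over the shifts, so overlapping Ugt1a genes are not the whole of it. The permutation p stayed at 0.0158, but it depends on the outermost genes as above and adds no support here. Without both 1753 libraries 5 of the 7 called genes passed: Ctse, and Ugt1a6a, Ugt1a5, Gm15369 and Gm15372 of the single Ugt1a locus. Fmod and D2hgdh did not (edgeR adjusted p = 0.155 and 0.0722). The pair alone thus does not account for Ctse and the Ugt1a locus, which leaves the other called loci open. The genes spread from Il1rl2 (start 40381472) to Esrrg (start 189432670), with 7 within 20 Mb of Hdac4 (permutation p = 0.00960). With neighbours counted once these were 3 loci (permutation p = 0.0246, and 0.185 for dKO against WT), so closeness to Hdac4 is less clear. A candidate explanation is strain DNA flanking the floxed Hdac4 allele, and another is loss of Hdac4 acting on these 16 genes. Neither was measured here. By design the floxed allele is in every dKO mouse, but how much strain DNA flanks it in each mouse is not known. The counts therefore do not tell these explanations apart. The chromosome was also picked after its values were seen.

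Thermogenic genes were higher in KO than in WT. With the muscle covariate 9 of the 10 genes that rose still passed, and 9 after thinning to a common depth, which argues against muscle RNA and depth as the whole cause. A higher share of adipocytes would raise adipocyte identity genes alike, but the third quartile of their log2 fold changes was 0.340, below the first quartile of the thermogenic list, 0.637. The list and the comparison were fixed before the data were examined. That LKB1 loss raises this program within adipocytes stays a hypothesis, since whole tissue was sequenced and the test of adipocyte share was chosen after the results were seen.

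Thermogenic genes lay mostly lower in dKO than in KO: 19 of 22 fold changes were negative, while only 2 genes passed singly with edgeR. By mean log2 CPM of the list the libraries overlapped, with 3.74 to 4.48 in KO and 3.04 to 3.81 in dKO. The KO libraries were also split between both comparisons. The thermogenic genes called with some of them had a median below 0 for dKO against the others in 20 of 20 fits (-1.58 to -0.157). This argues against genes picked for chance highs in the libraries that called them. A chance rise of the list across the KO mice would stay in both parts, so the fits cannot test it. The fits reuse the same libraries and are not independent, and chance levels in the dKO libraries stay in all of them. A lower share of adipocytes would lower adipocyte identity genes, whose first quartile was 0.0342, above the thermogenic median of -0.42; without both 1753 libraries these were -0.367 and -0.834. Without that pair the third quartile of the thermogenic list was -0.373, while Ucp1 itself, the measure first looked at, had a log2 fold change of -2.27 and did not pass (adjusted p = 0.185; 2.01e-06 to 0.185 over the alternatives). That HDAC4 carries part of the rise seen without LKB1 is a hypothesis, and the list did not pass with an estimated correlation (adjusted p = 0.382, and 0.126 without both 1753 libraries).

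Other splits of the libraries rarely gave as many genes. For KO against WT, 1 of 100 splits, the real one, gave 76 or more, and the highest other gave 2. For dKO against KO 3 of 100 gave 9 or more, the highest other 920, and for dKO against WT 2 of 100 gave 75 or more, the highest other 379. Both of these put 1753 and 1753-2 on one side and point to a structure of the samples beyond genotype. For opposite changes 1 of 100 gave 2 or more (highest other 0, with edgeR), and for any difference 2 of 100 gave 84 or more (highest other 308). With 1753 and 1753-2 as 2 mice, chance can be excluded at the 0.05 level, with no adjustment over the counts, for all of these but the opposite changes. The splits for opposite changes also break up the difference of KO from WT, so genes could hardly pass both ways in them. They do not test chance levels in the KO libraries that both comparisons share. With the pair summed to 1 mouse, 2 of 100 splits gave the 4 genes of dKO against KO or more (highest other 277), 1 of 100 the 26 of dKO against WT (highest other 12) and 1 of 100 the 72 with any difference (highest other 22), so chance can be excluded for these too. Opposite changes were then 0 with edgeR (137 genes at both unadjusted p under 0.05), and chance was not excluded for that count in either case.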
